A study of Mus musculus with 6 samples.

How the data were processed

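The 6 libraries were made from total RNA of mouse ocular lenses at postnatal day 0, 3 from WT and 3 from Fyco1-/- mice, each a biological replicate of pooled lenses. Per the labels, libraries were prepared with the NEB Next Ultra kit and sequenced as paired reads on a HiSeq. The authors aligned the reads to GRCm38/mm10 with STAR 2.5, counted them per gene with HTSeq 0.6.1 and turned the counts into FPKM values, 1 column per library. The total used for the scaling, the gene annotation and the handling of strand are not stated. The authors also deposited log2 fold changes of Fyco1-/- over WT from DESeq2 (release not stated), which look shrunken toward 0. The p-value and adjusted p-value columns were deposited by the authors from the same DESeq2 run and are blank for some genes. No count table was used, since the deposited table holds FPKM only.

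The table has 22298 entries, 21 of whose symbols occur more than once, and 93.1% matched 1 gene of GENCODE release M21 by symbol, from which positions, exon lengths and GC content were taken. The depth was estimated from the steps between small FPKM values, taking exon lengths from that release. Of 32749 values of 1 to 20 reads, 50.8% fell within 0.05 of a whole read, where 10% would by chance. The deepest library had 1.17 times the reads of the shallowest, and summed FPKM ran from 741913 to 760459. Depths are therefore estimates, and no intervals based on counts are given.

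Genes with a mean FPKM of at least 0.5 over the 6 libraries were tested (12001) with limma 3.58.1 in R 4.3.3, on log2(FPKM + 0.5), with trend and robust moderation and genotype as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Log2 fold changes are on that scale, so they understate the ratio of low genes, whereas fold values in the text are ratios of mean FPKM. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so single genes rest on the limma model, which pools spread across genes. The letters A, B and C do not pair the libraries (correlations of deviations -0.03, 0.03 and 0.03 for A, B and C), so they entered only as an alternative. Simulated data had 200 changed genes in each of 5 runs, with noise drawn independently for each gene. Changes were added to log2(FPKM + 0.5), so these folds are of FPKM + 0.5 and mean larger FPKM ratios in low genes. The same steps recovered 22.8% of changes of 1.25-fold, 66.0% of 1.5-fold, 83.2% of 2-fold and 98.0% of 4-fold. On average 4.75% of the calls were false.

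Gene lists, named genes, the test and most alternatives were fixed before the data were examined. The 39 lists cover crystallins, lens fibre structure, lens transcription factors, lens epithelium, organelle breakdown, autophagy (initiation, receptors, transport), lysosome, endoplasmic reticulum stress, ATF4, NRF2, heat shock, proteasome, oxidative phosphorylation (nuclear and mitochondrial), glycolysis and hypoxia, cell cycle, p53, cholesterol synthesis, lens capsule, epithelial-mesenchymal change, FGF, Notch, interferon, immediate early genes, ribosomal proteins, neighbours of Fyco1, markers of 10 other tissues or of sex, and RNA without a poly(A) tail. Lists with at least 3 tested members (38) were tested with limma's camera against all other tested genes, with a preset correlation of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, were the alternatives. Some genes stand in more than 1 list, such as Jag1, Hsf4, Pax6 and Tfap2a. Counts "adjusted over the list alone" adjust p over the members of that list.

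The named genes (125) are Fyco1, the 12 largest rises and 12 largest falls among called genes, the 6 most abundant called genes of each direction, and up to 4 called members of each list by p, or 2 members where none is called. Predicted or clone names were left out of the first groups, and named genes of those had to have all 3 values of 1 genotype above the other's. The text gives the main ones and adds a few, such as Bfsp1, Caprin2, Eif3j1, Tuba1a, Gm8210 and the neighbours of Bfsp2, chosen after their values were seen. The longest transcripts of tested genes were compared with each other, and not with the rest of the genome, by blastn 2.17.0, and a partner is near-identical at 95% identity or more over at least 100 bases (94.7% of tested genes could be searched). Of the 125 named genes 21 have such a partner, and 16 overlap exons of another gene by at least 50 bases.

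Alternatives changed 1 choice at a time: pseudocounts of 0.1 and 1, no filter on low values, at least 1 FPKM in 3 libraries, no robust moderation, an added bound of 1 on the log2 fold change, quantile normalization, median-of-ratios scaling, crystallins left out before scaling, the replicate block, and each library left out in turn. Rescaling to TPM, removing trends on GC content and length, leaving out chromosome 9 and leaving out genes with a near-identical partner were chosen after seeing the data. DESeq2, limma-voom and the count scalings planned for a count table were not run. Figures and other tests used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.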

Results

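RNA was sequenced from the ocular lenses of newborn mice at postnatal day 0. The lens is a transparent tissue in which a front layer of epithelium supplies fibre cells that fill with crystallins and lose their organelles. Lenses of wild-type (WT) mice were set against lenses labelled Fyco1-/-, with 3 libraries per genotype, each prepared from pooled lenses of the labelled strain C57BL/6. Every value is an FPKM, which per the labels counts fragments per kilobase of gene and is scaled to mapped reads. The table gives no read counts, but its smallest steps place the libraries at an estimated 17.1 M (A), 20.1 M (B) and 17.4 M (C) reads for WT. The estimates for Fyco1-/- are 18.9 M (A), 19.5 M (B) and 19.0 M (C) reads. One read in a gene of 1 kilobase then equals 0.0498 to 0.0585 FPKM. Crystallin transcripts made up 70.2% to 71.7% of the summed FPKM in every library. Across genes, which are not independent replicates, the log2 values of libraries of 1 genotype correlated at 0.990 to 0.991 and those of different genotypes at 0.978 to 0.982.

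The comparison asks which transcripts differ in newborn lenses when Fyco1 is disrupted. Fyco1 encodes an adaptor that links autophagosomes to the kinesin motors that carry them along microtubules. Fyco1 itself (ENSMUSG00000025241, GRCm38 chromosome 9, 123789500 to 123851899, minus strand) measured 5.40, 5.21 and 5.11 FPKM in WT A, B and C. It measured 4.61, 4.59 and 4.87 FPKM in Fyco1-/- A, B and C. The log2 fold change was -0.15 (SE 0.08, limma adjusted p = 0.273). The 3 values of the libraries labelled Fyco1-/- lay below the 3 of WT, but the difference was not called, so this level does not settle their genotype. The values sum over the whole gene, and the table shows neither exons nor alleles.

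In the Fyco1-/- libraries Bfsp2, which encodes the beaded filament protein phakinin of fibre cells, fell from 1736 ± 42.5 to 91.9 ± 21.1 FPKM (mean ± SD, n = 3 libraries per genotype, as for every mean here). Sptb, which encodes a beta spectrin of the membrane skeleton, fell from 77.0 ± 2.19 to 38.3 ± 0.529 FPKM. Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, rose from 237 ± 6.67 to 501 ± 43.6 FPKM. The autophagy receptor gene Sqstm1 rose from 42.3 ± 0.811 to 61.8 ± 4.05 FPKM, and the glycolytic enzyme gene Ldha fell from 87.3 ± 11.1 to 44.1 ± 2.84 FPKM. Of 12001 genes tested, 410 rose and 602 fell (limma, 1012 calls, 8.43% of the genes), and 2930 had an unadjusted p under 0.05. The median size of the called log2 fold changes was 0.42, and 82 called genes changed by at least 1 on that scale, 41 in each direction. All 1012 called genes had 3 values of 1 genotype above the 3 of the other, as did 29.7% of all tested genes, where chance gives 10%. The balance of directions depended on the scaling, since 40.5% of the calls were higher here and 56.5% with median-of-ratios scaling. Without WT A, WT B, Fyco1-/- B or Fyco1-/- C the number of calls was 612, 607, 673 or 642.

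**Figure D1:**
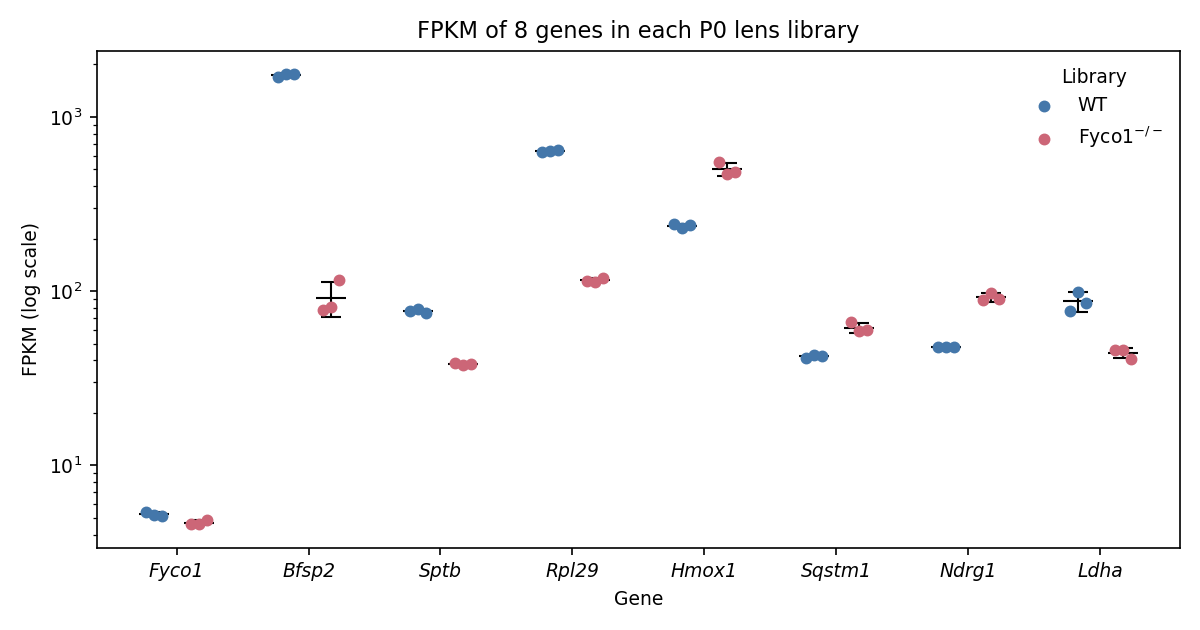
FPKM (log axis) of 8 genes in each library, with 3 WT and 3 Fyco1-/- libraries per gene; bars give the mean and SD. Bfsp2 lies at 1736 FPKM in WT and 91.9 FPKM in Fyco1-/-, while Fyco1 lies at 5.24 and 4.69 FPKM.

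Among fibre cell genes the fall of Bfsp2 stood apart from its partner in the beaded filament. Bfsp2 (ENSMUSG00000032556, GRCm38 chromosome 9, 103424924 to 103480420) had a log2 fold change of -4.26 (SE 0.16, adjusted p = 0.000141), with 78.3, 81.2 and 116 FPKM in Fyco1-/- A, B and C. Bfsp1, whose product filensin pairs with phakinin, measured 3200.5 FPKM in WT and 3315 FPKM in Fyco1-/- (log2 0.05, adjusted p = 0.439). Of 25 tested genes of fibre membrane, cytoskeleton and differentiation, 1 rose and 6 fell (3 and 8 adjusted over the list alone). The list as a whole was not called by camera (adjusted p = 0.445) but was called lower by fry (adjusted p = 0.00949). Its median log2 was -0.02, with 11 positive and 14 negative values, while its mean, which includes Bfsp2, was -0.29. Whether the fry call holds without Bfsp2 was not tested. Besides Bfsp2, Sptb fell 2.01-fold (adjusted p = 9.32e-07) and the cell cycle inhibitor gene Cdkn1c 1.30-fold (adjusted p = 0.000147). Caprin2 rose from 339 to 389 FPKM (log2 0.20, adjusted p = 0.00756). Of Bfsp2, 201 of the 1698 exon bases overlap a transcript of the opposite strand, 5830418P13Rik.

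The crystallin genes, which encode the main soluble proteins of the lens, went in both directions. Of 16 tested, 5 rose and 3 fell (6 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.116, but 0.0351 without WT C). The crystallins list was also called higher without genes that have a near-identical partner (mean difference 0.19 against 0.13, adjusted p = 0.0198), a setting chosen after seeing the data. Crygd and Crygf, named here, have such partners. Cryga rose 1.87-fold from 1527 ± 106 to 2856 ± 254 FPKM (adjusted p = 0.000341) and Crybb2 1.45-fold from 1873 ± 123 to 2712 ± 144 FPKM (adjusted p = 0.00046). Crygb rose from 42212 ± 635 to 50242 ± 1022 FPKM (log2 0.25, adjusted p = 0.00013), Crygc by a log2 of 0.18 (adjusted p = 0.00277) and Cryab by a log2 of 0.15 (adjusted p = 0.00961). Crygf fell from 36507 ± 657 to 31279.9 ± 595 FPKM (log2 -0.22, adjusted p = 0.000298). Crygd, the most abundant of the called genes, had a log2 fold change of -0.09 (adjusted p = 0.0418) and lost its call without any single library other than Fyco1-/- A (adjusted p = 0.0672 to 0.155). With median-of-ratios scaling its log2 fold change was -0.04 (adjusted p = 0.684). The calls of Crygf (adjusted p = 0.0686) with median-of-ratios scaling, of Crybb2 (adjusted p = 0.0677) with quantile normalization and of Crygc (adjusted p = 0.0518) with trends on GC content and length removed, a setting chosen after seeing the data, were also lost.

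Of 15 tested epithelium genes, none rose and 5 fell (0 and 9 adjusted over the list alone). The integrin gene Itga6 fell from 55.2 ± 2.01 to 33.9 ± 1.88 FPKM (adjusted p = 4.97e-05), and the Wnt antagonist gene Sfrp1 from 285 to 244 FPKM (adjusted p = 0.00185). The epithelium list was called lower (camera adjusted p = 0.0275, median log2 -0.20; adjusted p = 0.709 with an estimated correlation), but not without WT A (adjusted p = 0.0575) or Fyco1-/- A (adjusted p = 0.0647). Of 22 genes of the lens capsule and basement membrane, none rose and 7 fell (1 and 10 adjusted over the list alone). The laminin gene Lamb1 fell from 44.5 ± 1.08 to 31.2 ± 1.55 FPKM (adjusted p = 0.000269). The collagen IV genes Col4a5 (log2 -0.39, adjusted p = 0.000643) and Col4a6 (log2 -0.35, adjusted p = 0.0011) and the nidogen gene Nid1 (log2 -0.30, adjusted p = 0.00421) also fell. That list was called lower (camera adjusted p = 0.00481, adjusted p = 0.709 with an estimated correlation).

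Of 22 lens transcription factor genes, 1 rose and 4 fell (1 and 9 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0594). The lens transcription factors list was called lower in 6 of 21 other settings, among them quantile normalization (adjusted p = 0.0198) and leaving out Fyco1-/- A (adjusted p = 0.0431). Hsf4, a heat shock factor needed for fibre maturation, rose from 145 to 171 FPKM (log2 0.24, adjusted p = 0.00235), and Pitx3, a homeobox factor of the early lens, fell from 85.3 to 69.0 FPKM (log2 -0.31, adjusted p = 0.00353). Of 19 genes tied to organelle breakdown in fibres, 3 rose and none fell (4 and 1 adjusted over the list alone). Among them, Trp53inp2 had a log2 fold change of 0.60 (adjusted p = 0.022). That list was not called (camera adjusted p = 0.638) and its median (log2 -0.12) and mean (log2 -0.02) had the opposite sign to its test, which pointed higher than other genes. Trp53inp2 lost its call without Fyco1-/- B (adjusted p = 0.0766) or Fyco1-/- C (adjusted p = 0.0674).

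The machinery of autophagy around Fyco1 changed in a few members. Of 22 selective autophagy receptor genes, which encode proteins that bring cargo to autophagosomes, 5 rose and none fell (6 and 2 adjusted over the list alone). Sqstm1 rose 1.46-fold (adjusted p = 0.000228), Optn 1.37-fold (adjusted p = 0.00354). The ER-phagy receptor gene Tex264 rose 1.20-fold (adjusted p = 0.00597) and Tax1bp1 1.19-fold (adjusted p = 0.0127). The receptor list was not called (camera adjusted p = 0.349), and its median (log2 -0.03) was opposite in sign to its mean (log2 0.03) and its test. Of 37 genes of autophagy initiation and LC3 conjugation, only Gabarapl1 rose, from 105 to 132 FPKM (adjusted p = 0.00083), and none fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.367). The list of autophagosome and endosome transport and fusion was called higher by camera (adjusted p = 0.0171, median log2 0.06, adjusted p = 0.676 with an estimated correlation) but not by fry (adjusted p = 0.134). Of its 32 tested genes, 2 rose and none fell (2 and 0 adjusted over the list alone). They were Vps11, a subunit of the tethering complexes of endosomes and lysosomes, from 8.81 to 13.2 FPKM (adjusted p = 0.00205), and Rab11a, from 48.2 to 56.2 FPKM (adjusted p = 0.0173). Rab11a lost its call without WT B (adjusted p = 0.0695), WT C (adjusted p = 0.0505), Fyco1-/- B (adjusted p = 0.0675) or Fyco1-/- C (adjusted p = 0.0548). Vps11, Rab11a and Tex264 lie on chromosome 9, as does Fyco1, while Sqstm1, Optn, Tax1bp1 and Gabarapl1 lie on other chromosomes. A larger share of tested genes was called on chromosome 9 (13.1%) than on the others (8.21%). Whether the calls of Vps11, Rab11a and Tex264 go with that chromosome or with the loss of Fyco1 was not tested.

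Of 47 lysosome genes, 2 rose and 5 fell (4 and 7 adjusted over the list alone), and the list was not called (camera adjusted p = 0.89, a test pointing higher while the median log2 was -0.03 and the mean -0.02). The protease gene Ctsl rose from 42.4 ± 4.84 to 64.4 ± 3.79 FPKM (adjusted p = 0.00185), and the protease gene Ctsf fell from 45.9 to 36.7 FPKM (adjusted p = 0.00438). The acid ceramidase gene Asah1 fell from 7.53 to 5.58 FPKM (adjusted p = 0.00838). Of 31 proteasome genes, 2 rose and none fell (4 and 0 adjusted over the list alone), Psmc1 from 114 to 131 FPKM (adjusted p = 0.00783). Small positive values in 28 of the 31 (median log2 0.11) gave a called list (camera adjusted p = 2.26e-05, adjusted p = 0.654 with an estimated correlation). The other proteasome call, Psmb1 (log2 0.14, adjusted p = 0.0403), was lost without any 1 of the 6 libraries (adjusted p = 0.0535 to 0.142).

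Of 30 NRF2 and glutathione genes, 2 rose and 6 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.902, with a mean 0.01 above other genes beside a test and median, log2 -0.06, that pointed lower). Hmox1 (ENSMUSG00000005413, GRCm38 chromosome 8, 75093621 to 75100589) rose 2.11-fold (log2 1.07, SE 0.06, adjusted p = 5.7e-06) and Ftl1, which encodes the light chain of the iron store ferritin, rose from 1217 ± 11.1 to 1549 ± 27.5 FPKM (adjusted p = 4.97e-05). The glutathione synthesis gene Gclc fell by 0.37 on the log2 scale (adjusted p = 0.00416). Of 18 genes of the cytosolic heat shock response, 3 rose and 2 fell (4 and 2 adjusted over the list alone). The co-chaperone gene Dnajb1 rose from 81.0 to 117 FPKM (adjusted p = 0.000125), and the chaperone gene Hspa8 fell from 307 to 243 FPKM (adjusted p = 0.00172). The list was called higher (camera adjusted p = 0.048, adjusted p = 0.709 with an estimated correlation), but not without WT A (adjusted p = 0.212), Fyco1-/- A (adjusted p = 0.216) or Fyco1-/- C (adjusted p = 0.0736). The call of the cytosolic heat shock response was lost in 11 of 21 other settings, among them quantile normalization (adjusted p = 0.228) and no filter on low values (adjusted p = 0.157). Of 28 genes of endoplasmic reticulum stress, none rose and 4 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.919). Pdia6, a protein disulfide isomerase gene, fell from 242 ± 4.52 to 163 ± 8.94 FPKM (adjusted p = 4.97e-05). Of 25 genes of the ATF4 and amino acid response, 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.686, a test pointing higher beside a median log2 of -0.04 and a mean of -0.05). The calls were Gars (log2 0.25, adjusted p = 0.0142), lost without WT B (adjusted p = 0.0573) or Fyco1-/- C (adjusted p = 0.0505), and Psat1 (log2 -0.26, adjusted p = 0.0285), lost without any single library other than Fyco1-/- A (adjusted p = 0.0537 to 0.106).

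Of 26 glycolysis and hypoxia genes, 2 rose and 14 fell (2 and 18 adjusted over the list alone), and the list was called lower (camera adjusted p = 5.03e-05, median log2 -0.31; adjusted p = 0.654 with an estimated correlation). Ldha fell 1.98-fold (adjusted p = 0.000298), Tpi1 from 112 to 77.6 FPKM (adjusted p = 0.000124) and Aldoa from 273 to 205 FPKM (adjusted p = 0.000141). Ndrg1, a gene induced by low oxygen, rose from 47.6 ± 0.133 to 92.2 ± 5.16 FPKM (adjusted p = 2.21e-06). Gapdh, often used as a reference gene, fell from 1245 to 1100.2 FPKM (adjusted p = 0.00243), a call lost with median-of-ratios scaling (adjusted p = 0.111). Of 71 nuclear genes of oxidative phosphorylation, 9 rose and 2 fell (10 and 4 adjusted over the list alone), with a called list (camera adjusted p = 9.23e-05, median log2 0.06; adjusted p = 0.654 with an estimated correlation). Among them the ATP synthase gene Atp5e rose from 108 to 128 FPKM (adjusted p = 0.00565) and the complex I gene Ndufb8 from 18.7 to 23.3 FPKM (adjusted p = 0.00865). Of 12 mitochondrially encoded genes none rose and only mt-Atp6 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.372, mean difference -0.11), by 0.34 on the log2 scale (adjusted p = 0.0195). That call was lost without WT A (adjusted p = 0.0757) or WT C (adjusted p = 0.0503). The mitochondrially encoded list was called lower with quantile normalization (mean difference -0.19, adjusted p = 0.0198) and with trends on GC content and length removed, a setting chosen after seeing the data (-0.23, adjusted p = 0.0125). None of 24 cholesterol synthesis genes was called (0 and 0 adjusted over the list alone, camera adjusted p = 0.919, a test pointing higher beside a median log2 of -0.05 and a mean of -0.04). Sc5d, which encodes a sterol desaturase, had a log2 fold change of -0.30 (adjusted p = 0.125).

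Of 40 cell cycle genes, 1 rose and 9 fell (2 and 12 adjusted over the list alone), and the list was called lower (camera adjusted p = 9.23e-05, median log2 -0.28; adjusted p = 0.709 with an estimated correlation), though not by fry (adjusted p = 0.074). The lens epithelium list was called lower too (camera adjusted p = 0.0275, median log2 -0.20; adjusted p = 0.709 with an estimated correlation). The replication genes Pcna (13.2 to 7.96 FPKM, adjusted p = 0.000746) and Mcm6 (2.31-fold, adjusted p = 0.00107) fell, as did the cyclin gene Ccnd2 (29.1 to 22.5 FPKM, adjusted p = 0.00436) and the mitotic kinase gene Aurkb (2.95 to 1.46 FPKM, adjusted p = 0.0107). Of 23 p53 targets and apoptosis genes, 1 rose and none fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.668). It was Sesn1 (log2 0.27, adjusted p = 0.0183), whose call was lost without WT B (adjusted p = 0.0651) or Fyco1-/- C (adjusted p = 0.0571). Of 75 ribosomal protein genes, 16 rose and 3 fell (24 and 4 adjusted over the list alone). Rps29 rose from 527 to 771 FPKM (adjusted p = 5.85e-05), Rpl38 from 601 to 822 FPKM (adjusted p = 0.000222) and Rplp1 from 1095 to 1417 FPKM (adjusted p = 9.38e-05). Rpl29, with the lowest p of the list, fell from 637 to 116 FPKM (adjusted p = 8.69e-11). The ribosomal list was called higher (camera adjusted p = 0.000182, median log2 0.05; adjusted p = 0.709 with an estimated correlation). That call was lost when genes with a near-identical partner among the tested genes were left out (adjusted p = 0.185), a setting chosen after seeing the data, though the mean difference from other genes stayed near its size, at 0.08 against 0.09. Rps29, Rpl38, Rplp1, Rpl29 and Pcna each have such a partner.

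Signalling and injury genes were called in small numbers. Of 15 genes of epithelial-mesenchymal change and injury, none rose and 2 fell (0 and 4 adjusted over the list alone), including the matrix gene Fn1, from 3.42 to 2.24 FPKM (adjusted p = 0.00738). That list was called lower (camera adjusted p = 0.0107, adjusted p = 0.654 with an estimated correlation). The markers of fibroblasts and periocular mesenchyme were lower as well, 5 of 5, with a median log2 of -0.43 (camera adjusted p = 0.0341, adjusted p = 0.654 with an estimated correlation). Of 17 FGF and ERK targets, none rose and 2 fell (0 and 2 adjusted over the list alone), among them the ERK phosphatase gene Dusp6, from 3.88 to 2.52 FPKM (adjusted p = 0.0107). The FGF list was called lower (camera adjusted p = 0.0473, adjusted p = 0.654 with an estimated correlation), but not without WT B (adjusted p = 0.0604), WT C (adjusted p = 0.0982), Fyco1-/- A (adjusted p = 0.0953) or Fyco1-/- C (adjusted p = 0.0507). Of 15 Notch pathway genes only the ligand gene Jag1 was called, falling from 67.6 to 57.1 FPKM (adjusted p = 0.00866), as when adjusted over the list alone (0 rose and 1 fell, camera adjusted p = 0.128, and 0.0358 for the Notch pathway with no filter on low values). Of 8 interferon response genes none rose and 1 fell (0 and 5 adjusted over the list alone), the antiviral gene Rsad2, from 1.49 ± 0.0626 to 0.0289 ± 0.0184 FPKM (adjusted p = 4.97e-05). That list was called lower (camera adjusted p = 0.0171, median log2 -0.65; adjusted p = 0.676 with an estimated correlation), but not when genes needed at least 1 FPKM in 3 libraries (adjusted p = 0.116). Of 18 immediate early genes 1 rose and 1 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.141, fry adjusted p = 0.0404). They were Dusp1 (log2 0.26, adjusted p = 0.0447), lost without any single library other than Fyco1-/- C (adjusted p = 0.0887 to 0.148), and Jund (log2 -0.28, adjusted p = 0.0248), lost without WT A, WT B or Fyco1-/- C (adjusted p = 0.0828 to 0.0851).

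On the scale of log2(FPKM + 0.5), the largest rises among called genes without a predicted, pseudogene or clone name were Eif3j2 (0.916 ± 0.219 to 19.0 ± 0.212 FPKM, 20.8-fold, adjusted p = 5.31e-08) and the tubulin gene Tuba1c (1.22 ± 0.307 to 11.3 ± 0.0255 FPKM, 9.22-fold, adjusted p = 1.33e-06). Each has a near-identical partner that fell, Eif3j1 (16.1 to 9.58 FPKM, adjusted p = 6.47e-05) and Tuba1a (724 to 621 FPKM, adjusted p = 0.00662). With no such partner found among the tested genes, Scfd2 rose from 1.81 ± 0.192 to 13.9 ± 3.57 FPKM (adjusted p = 4.97e-05) and Slc45a4 from 1.28 to 5.66 FPKM (adjusted p = 3.76e-06). The secreted factor gene Prok2 rose from 0.280 to 2.13 FPKM (adjusted p = 0.000298) and the water channel gene Aqp3 from 0.172 to 1.35 FPKM (adjusted p = 0.000543). Rab4a, Efcab8 and Mt1 also rose, with log2 fold changes of 1.43, 1.14 and 1.28, Cenpv by 1.69 and Hist1h2bq by 1.77. Mt1 lost its call without WT B (adjusted p = 0.0542), and Cenpv without WT B (adjusted p = 0.0552), Fyco1-/- B (adjusted p = 0.0607) or Fyco1-/- C (adjusted p = 0.0597). Hist1h2bq has a near-identical partner in Hist1h2bc, which fell by 0.31 on the log2 scale (adjusted p = 0.00387).

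On the same scale, and again among called genes with such names left out, the largest falls after Bfsp2 were Ankrd34c (5.23 ± 1.03 to 0.220 ± 0.308 FPKM, log2 -3.06, adjusted p = 0.000339) and the ribosomal protein gene Rpl29 (637 ± 11.4 to 116 ± 3.40 FPKM, log2 -2.45, adjusted p = 8.69e-11). Ndufs5, which was not called, had a log2 fold change of -3.00 (117 ± 7.76 to 17.4 ± 13.5 FPKM, limma adjusted p = 0.0753). Its near-identical copy BC002163 rose from 1.39 ± 0.395 to 153 ± 15.7 FPKM (limma adjusted p = 2.47e-07). A shift of reads between the 2 was not tested apart from a change of Ndufs5 itself. The Rpl29 copy Gm8210, identical at 99.5% of 422 aligned bases, went the other way, from 0.120 ± 0.119 to 33.7 ± 1.08 FPKM (adjusted p = 4.87e-09). Large falls were also seen in the uridine phosphorylase gene Upp1 (4.41 to 0.683 FPKM, adjusted p = 0.005) and the transporter gene Abca13 (1.58 to 0.0906 FPKM, adjusted p = 0.000124). Others were the cohesin gene Rec8 (1.35 to 0.119 FPKM, adjusted p = 0.000269), the securin gene Pttg1 (4.57 to 1.29 FPKM, adjusted p = 9.38e-05) and the myosin gene Myo7a (1.29 to 0.157 FPKM, adjusted p = 0.000486). Zfp125 and Rgs4 had log2 fold changes of -1.51 and -1.40. Col6a3 fell from 11.2 ± 0.593 to 3.11 ± 1.86 FPKM (adjusted p = 0.0316), a call that was lost without any single library other than Fyco1-/- A (adjusted p = 0.0707 to 0.122). Ankrd34c, Bfsp2, Rpl29 and Fyco1 all lie on chromosome 9, and none of 11 tested neighbours of Fyco1 was called (0 and 0 adjusted over the list alone, camera adjusted p = 0.919). The lowest p values among these neighbours were those of Lars2 (log2 0.62, adjusted p = 0.123) and Kif15 (log2 -0.43, adjusted p = 0.127), which were called without WT A (adjusted p = 0.00187) and without WT C (adjusted p = 0.0489), respectively. Lars2 was also called without robust moderation (adjusted p = 0.0361). On chromosome 9, 83 of 634 tested genes were called (13.1%), against 8.21% on the other chromosomes (Fisher's exact test, two-sided, adjusted p = 0.00102). It was the only 1 of 20 chromosomes to pass, in a test chosen after seeing the data.

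**Figure D2:**
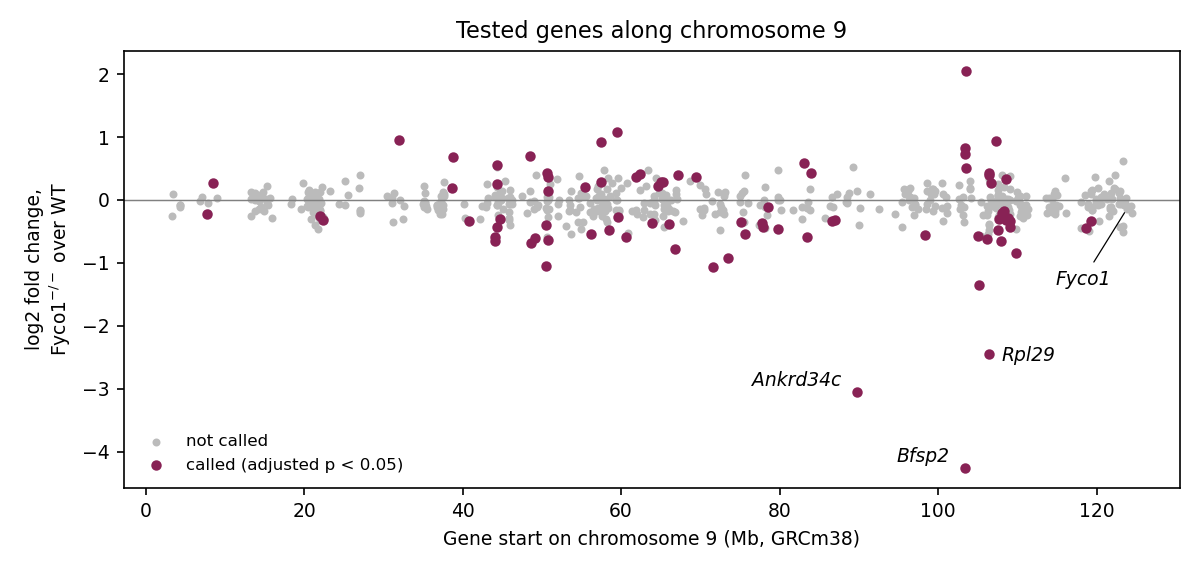
Log2 fold change (Fyco1-/- over WT) of each tested gene against its start on GRCm38 chromosome 9 in Mb; coloured points passed the limma adjusted p threshold. Bfsp2 (-4.26), Ankrd34c (-3.06) and Rpl29 (-2.45) lie lowest, and Fyco1 (-0.15) lies near the end.

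**Figure D3:**
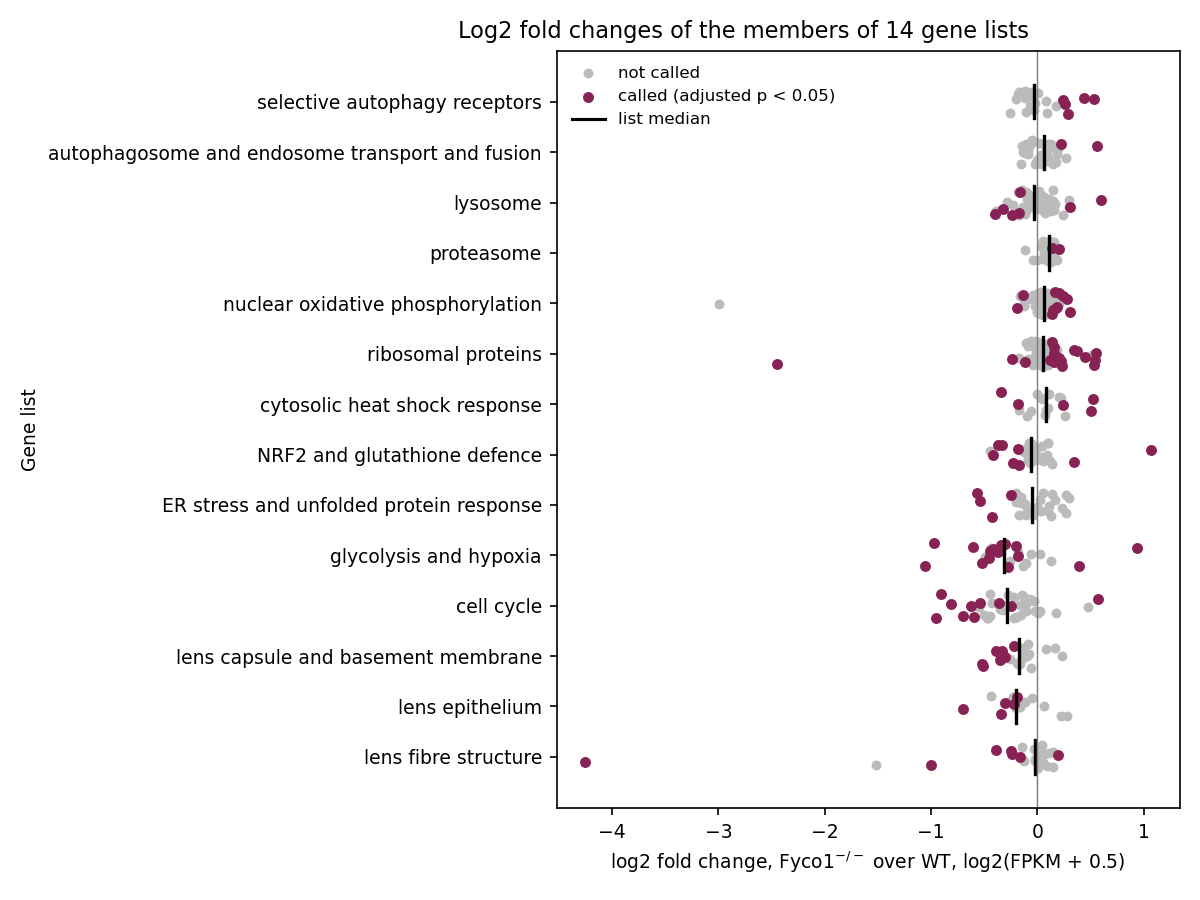
Log2 fold change (Fyco1-/- over WT, on FPKM + 0.5) of each tested member of 14 gene lists; coloured points passed the limma adjusted p threshold and black bars mark list medians. The glycolysis and hypoxia list has a median of -0.31 and the proteasome list one of 0.11.

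Markers of other tissues passed the filter on low values to differing extents, from 4 of 23 for retina and neurons to 8 of 12 for skeletal muscle and 16 of 16 for vessel endothelium. Most that were tested lay lower in Fyco1-/-, where the median of all tested genes also lay below 0 (log2 -0.04). Of 5 genes of fibroblasts and periocular mesenchyme none was called (0 and 4 adjusted over the list alone), with Foxc1 at 2.03 and 1.39 FPKM (log2 -0.43, adjusted p = 0.0577) and Col1a1 at 0.976 and 0.352 FPKM (log2 -0.77, adjusted p = 0.0697, and 0.045 without WT B). That list was called lower (camera adjusted p = 0.0341, adjusted p = 0.654 with an estimated correlation), but not without WT C (adjusted p = 0.0706) or Fyco1-/- A (adjusted p = 0.0786). The call was also lost when genes needed at least 1 FPKM in 3 libraries (mean difference -0.19 against -0.35, adjusted p = 0.163). Removing trends on GC content and length, a setting chosen after seeing the data, ended it too (adjusted p = 0.0686). Of 8 skeletal muscle genes none was called (0 and 0 adjusted over the list alone). The muscle list was called lower (camera adjusted p = 0.0369, adjusted p = 0.709 with an estimated correlation), but not without Fyco1-/- A (adjusted p = 0.115) or Fyco1-/- B (adjusted p = 0.0784). The muscle actin gene Acta1 measured 4.61, 21.7 and 3.49 FPKM in WT A, B and C against 0.778 to 1.69 FPKM in the Fyco1-/- libraries (adjusted p = 0.162, and 0.00738 without WT B). Myl1, a muscle myosin gene, had a log2 fold change of -1.60 (adjusted p = 0.25). Of 16 vessel endothelium genes only Plvap was called, at a log2 of -0.52 (adjusted p = 0.0195; 0 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.36). It lost the call without WT A, WT B, Fyco1-/- A or Fyco1-/- C (adjusted p = 0.0528 to 0.0708). Of 4 genes of pigment epithelium, ciliary body and melanocytes only Bmp7 was called, at a log2 of -0.39 (adjusted p = 0.0346; 0 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.749). That call was lost without any single library other than WT C (adjusted p = 0.0668 to 0.124).

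No gene was called among 4 of retina and neurons (0 and 1 adjusted over the list alone, camera adjusted p = 0.372). Atoh7 had a log2 fold change of -0.59 (adjusted p = 0.0521) and Tubb3 of -0.39 (adjusted p = 0.329). None was called among 8 of pericytes and smooth muscle (0 and 0 adjusted over the list alone, camera adjusted p = 0.638), with Abcc9 at a log2 of -0.48 (adjusted p = 0.0861) and Tagln at -0.39 (adjusted p = 0.198). Among 8 of macrophages and other leukocytes none was called (0 and 0 adjusted over the list alone, camera adjusted p = 0.919), with Pf4 at 0.74 (adjusted p = 0.0996, and 0.0251 without WT C) and Ctss at -0.55 (adjusted p = 0.387). The 6 red blood cell genes gave no call (0 and 0 adjusted over the list alone, camera adjusted p = 0.919), with Hbb-bt at -1.13 (adjusted p = 0.354, and 0.00922 without Fyco1-/- A) and Hba-a2 at -0.60 (adjusted p = 0.43). The 5 genes of a list of Y-linked genes and Xist gave no call (0 and 0 adjusted over the list alone, camera adjusted p = 0.399), with Eif2s3y at 0.73 (adjusted p = 0.314) and Ddx3y at 0.24 (adjusted p = 0.669). Only 2 of 12 genes of cornea and surface epithelium could be tested, too few for a list, and neither Perp (log2 -0.20, adjusted p = 0.119) nor Krt15 (log2 0.23, adjusted p = 0.706) was called. Of 5 tested genes of the list named RNA without a poly(A) tail, a property not measured in these libraries, none rose and 2 fell (0 and 3 adjusted over the list alone). They were the histone genes Hist1h1e (log2 -0.62, adjusted p = 0.00357) and Hist1h2bc (log2 -0.31, adjusted p = 0.00387). That list was called lower (camera adjusted p = 0.0275, adjusted p = 0.654 with an estimated correlation), but not without WT C (adjusted p = 0.0706) or Fyco1-/- C (adjusted p = 0.0611), nor without genes that have a near-identical partner (adjusted p = 0.288). In that last setting the mean difference did not shrink (log2 -0.68 against -0.58) and fewer members were left. In all, 15 of 38 lists were called with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.654), while fry called 9 of the 15 and 2 others. Besides cell cycle, fry did not call transport and fusion (adjusted p = 0.134), lens capsule (adjusted p = 0.0515), ribosomal proteins (adjusted p = 0.353), heat shock (adjusted p = 0.353) or skeletal muscle (adjusted p = 0.302). With the preset correlation, the 9 other splits of the 6 libraries into groups of 3 called 3 to 12 lists each. Those splits mix the genotypes in unequal shares, so part of the genotype difference remains in them.

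The authors' deposited table gives its own DESeq2 values for the same libraries. In the authors' deposited table, 1224 genes have an adjusted p under 0.05, of which 55.7% are higher in Fyco1-/-. Of the 1012 genes called here, 798 are among them, all 798 with the same sign. For Bfsp2 the authors' deposited table lists a log2 fold change of -2.88 (adjusted p = 7.71e-77), and for Fyco1 -0.10 (adjusted p = 0.553). Of the 24 named genes with the largest rises and falls, 22 also have an adjusted p under 0.05 in the authors' deposited table. The exceptions are Ankrd34c (log2 -0.22, adjusted p = 0.11 in the authors' deposited table) and Zfp125, which has no adjusted p there.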

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

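Chosen only after the result was seen were the TPM rescaling, the removal of trends on GC content and length, and leaving out chromosome 9 or genes with a near-identical partner. The count of called genes (1012) stayed within 1.5 times under each alternative except 568 with no filter on low values, which tested 22298 genes and shared 544 calls, 82 with an added bound of 1 on the log2 fold change, and 607, 612, 642 and 673 without WT B, WT A, Fyco1-/- C and Fyco1-/- B. Leaving out single libraries gave 607 to 863 in all. The share of calls that were higher (40.5%, binomial 95% interval 37.5% to 43.6%) went to 56.5% with median-of-ratios scaling, 50% with the added bound, 48.1% with quantile normalization, 35.8% with TPM rescaling, and 35.1% to 46.9% when single libraries were left out. The median log2 fold change over all tested genes was -0.043 here, and -0.003 both with median-of-ratios scaling and with quantile normalization. A shift of this size thus went with a change in the balance, as many called changes are small. In the authors' deposited table, from DESeq2, 55.7% of the calls are higher. More calls fell than rose with quantile normalization (528 higher, 569 lower), crystallins left out before scaling (438, 609) and TPM rescaling (343, 614). Median-of-ratios scaling reversed this (627, 483). The excess of falls among the calls here therefore depends on the scaling. Whether it is a result about the genotypes cannot be decided from these values, as each scaling fixes the total or middle level in its own way. Beyond the scaling itself the cause was not tested. Fyco1 was called under no alternative (log2 -0.17 to -0.09, adjusted p = 0.258 to 0.506). With an estimated correlation 0 of the 15 called lists passed, while fry called 9 of the 15 and 2 others. With the letters as a replicate block there were 929 calls, 822 of them shared, and Lars2 was called (adjusted p = 0.00581). Of 104 called genes named by the rule other than Fyco1, 69 kept their direction and call under each alternative that tested them, apart from the added bound, which ends every call under 1 by construction, and 35 lost the call under at least 1; of 20 uncalled ones 8 gained a call, and none of these genes changed sign when called. With no filter on low values 21 of the 104 lost their call, among them Rab11a, Trp53inp2 and Plvap. With quantile normalization Crygd, Crygc, Cryab and Crygs hold the same rank in every library, so their change is set to 0 by construction. The count-based alternatives were not run, as no counts were used, and scaling by library totals alone is what FPKM already holds. On simulated data 66.0% of 1.5-fold changes of FPKM + 0.5 were recovered, so small changes that were not called may still be present at this depth.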

Other observations

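The tests of other splits, of copies and partners, of chromosome positions, of the other fibre genes, of skeletal muscle and of lens epithelium were chosen only after the result was seen. The test of GC content and length was also added after seeing the data, but written down before its own result. Near Bfsp2 on chromosome 9 the adjacent genes went the other way. Cdv3 rose from 72.7 ± 3.76 to 121 ± 2.60 FPKM (n = 3 libraries per genotype, limma adjusted p = 1.06e-05), Tmem108 from 2.25 to 3.40 FPKM (adjusted p = 0.0143), the opposite-strand transcript 5830418P13Rik from 7.54 to 13.6 FPKM (adjusted p = 0.00105), and Gm16252 from 0.235 to 2.59 FPKM (adjusted p = 4.97e-05). Within 10 Mb of Bfsp2, 25 of 151 other tested genes were called (16.6%, exact binomial 95% interval 11.01% to 23.5%). That interval lies above the 8.43% of all tested genes but includes the 13.1% of all chromosome 9 genes. The window was set around a gene chosen for its fall. Of 325 tested pseudogenes 37 were called, 26 of them higher.

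Of the 10 splits of the 6 libraries into groups of 3, 1 gave 1012 called genes, the real one, and the highest other gave 0. For lists, the real split gave 15, and the other 9 gave 3 to 12 though none of them called a gene. With 10 splits no share under 0.1 can arise, so these counts are too few for a test. The groups of each other split hold the genotypes in unequal shares, so part of the genotype difference remains between them and part adds to the spread within them. List calls in such splits are therefore no measure of false calls, and the lack of gene calls is none either. Whether a list call by camera with the preset correlation alone marks a difference between the genotypes cannot be read from these splits.

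Of the 41 genes that rose by at least 1 on the log2 scale, 21 have a near-identical partner (51.2%), against 9.54% of the 10989 uncalled genes (Fisher's exact test, two-sided, p = 1.74e-11) and 19.5% of the 41 that fell as far. The median of the summed change of copy and partner divided by the gain of the copy was -1.63 (bootstrap 95% interval over copies -6.94 to 0.12). This cannot decide whether the copies themselves were transcribed more, because a fall of a far more abundant partner outweighs the gain of its copy. Tuba1a, for example, lost 186 FPKM times kilobases while Tuba1c gained 23.0. A shift of reads from an abundant partner to its copy stays open as well. For 15 of the 21 copies the most abundant partner was called lower, against 43 of 1048 uncalled genes. With each partner counted once, it was 13 of 19 against 23 of 559 (Fisher's exact test, one-sided, p = 4.41e-13). The negative median means that most partners lost more than their copies gained, as for Rpl29, which lost 586 FPKM times kilobases while Gm8210 gained 16.2 and Gm13841 11.97, so such a shift leaves most of the fall of Rpl29 unaccounted for. A candidate explanation is a sequence variant or an alignment difference between the genotypes, which reads rather than FPKM would be needed to see.

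Bfsp2 fell 18.9-fold on a chromosome that also carries Fyco1, and deletions of Bfsp2 are known in some inbred strains, though the labels give C57BL/6 for all libraries. A general fall of fibre transcripts is argued against by the other 24 fibre genes, with a median log2 fold change of -0.016 (SD 0.38). A segment of another strain through Fyco1 stays open, with no excess of calls in its favour: within 10 Mb, 2 of 69 genes were called (2.90%, exact binomial 95% interval 0.353% to 10.1%), an interval that includes the 8.52% of other genes. Segments elsewhere stay open too. Pairs of called genes 1 to 10 Mb apart numbered 4053 against 3841 in shuffles (one-sided permutation p = 0.07), and 3413 against 3393 without chromosome 9 (p = 0.436). Adjacent called genes, which can also share regulation or exons, made 142 pairs against 81.5 in shuffles. Without chromosome 9 they made 127 against 72.0 (both one-sided permutation p = 0.0005, the smallest that 2000 shuffles can give). The other splits called no gene, so in each of them as many top genes (963) were paired instead. Those genes were ranked by the size of their difference over its error and not by limma, which is an unlike measure. They gave up to 4103 pairs 1 to 10 Mb apart and up to 106 adjacent pairs. A segment around Bfsp2 that ends before Fyco1, and a response of Bfsp2 to the loss of Fyco1, could each give these values, and neither was tested.

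The fall of glycolysis and hypoxia genes was weighed against 3 explanations. A trend on GC content or length is argued against, since with both removed the list's mean difference was -0.21, against -0.23 before (camera adjusted p = 0.000104). Less skeletal muscle RNA in the Fyco1-/- libraries is argued against as well, because 8 muscle genes were lower by 24.1 FPKM in sum, 4.15% of the 580.3 FPKM lost by the 14 called glycolytic genes. A lower share of epithelium cannot be told apart from a change within cells. The 15 epithelium genes, called or not, had a median log2 fold change of -0.20 (SD 0.24). All 26 tested glycolysis and hypoxia genes had a median of -0.31. The 14 called lower had one of -0.39, but they were picked for their fall, so that value is not like for like. The response to genotype within lens cells may also account for the fall and was not tested.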
